A study of Mus musculus with 72 samples.

How the data were processed

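Expression was measured on 72 arrays of mouse colon, 1 per mouse, and the deposited table gives 1 value per probe set and array on a log2 scale, normalised by the authors. The unit of log2 was taken from the deposited values, which run from a floor of 2.077 upwards. Per the submitters' processing notes, RMA, GCRMA, R 2.11.1 and limma 3.4.5 were used; which of these steps made the table is not given in the sources used here. Array medians lay between 4.60 and 4.77, between 36% and 37.84% of probe sets per array were within 0.1 of the floor, and the 3 prime minus 5 prime difference of Actb, a measure of RNA quality, ranged from 0.93 to 1.50. This difference is larger where RNA is more degraded. No array was removed. The first naive replicate carries contradictory labels and was kept as naive, as its title and source name state.

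The table holds 45101 probe sets: 34945 map to 1 gene symbol, 932 to several, 9160 to none, and 64 are Affymetrix controls. Probe sets with 1 symbol were kept, symbols were updated by Entrez identifier (99.4% matched), and each of the 18193 genes was represented by its probe set with the highest mean. Genes whose mean lay below the 40th percentile of all probe set means (2.42) were left out, which left 12534. Of 10 pathway genes set to be named in any case 7 were tested; Tnf was too dim, Tnfsf12 is covered only by probe sets of several genes, and Nfkb1 was not analysed here.

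A linear model with a term for each of the 6 groups and a term for the experiment was fitted to all arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and two-sided tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Departure from additivity was the contrast combination minus TNFR-Ig minus anti-TWEAK plus control antibody, which does not cancel an effect of the antibody, since TNFR-Ig mice received none. Contrasts that cancel it, with untreated mice, were added after the data were seen. Differences of an effect between experiments were tested as interactions. The 31 gene lists (545 members, 430 tested) were compared with all other genes by camera with a preset correlation of 0.01 and again with the correlation estimated for each list. The colitis score used genes called in the comparison of untreated and naive mice with an absolute log2 change of at least 1. Its differences were tested by 100000 permutations within experiments, and by exact permutation inside each experiment, two-sided. Groups, comparisons, lists, the score and the rule for named genes were set before the data were examined. By this rule, among genes called with the same sign in both experiments where both hold the groups, a comparison names the 8 largest rises and the 8 largest falls, up to 4 called members of each list by size of change, and the pathway genes. Where fewer than 5 genes are called, the 5 with the smallest p are named as not passing, and predicted genes and clone names are counted but not named. Genes outside it are said to have been chosen after their values were seen.

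The procedure was tested on simulated data for 4 of the 8 comparisons, 20 times each, with 200 genes changed. For changes of 0.5, 1 and 2 log2 units it recovered 85%, 96.3% and 98.9% of them in the combination comparison, 83.1%, 95.6% and 98.7% for TNFR-Ig, 72.1%, 91.9% and 97.3% for departure from additivity, and 74.3%, 92% and 97.7% for colitis. On average 3.12%, 5.6%, 3% and 2.59% of calls were false. The highest number of false calls in a simulation was 60, 101, 59 and 42, which for additivity is above the 40 genes called in the data. The simulations mixed the residuals of all groups within each experiment, so the simulated groups shared 1 spread. The real groups did not: the SD of the colitis score was 0.076 in naive and 1.13 in anti-TWEAK mice. These shares of false calls therefore do not measure the error under unequal spread. With no list changed, camera with the preset correlation called at least 1 list in 19 of 20 simulations (median 6.5 lists for the combination and 7.5 for colitis), and with the estimated correlation in 0, so that list results with the preset correlation alone are weak evidence.

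Alternatives tried were no filter on dim genes, testing every probe set, no experiment term, a block for replicate number, each experiment alone, quantile normalization, array weights, a fit of the compared groups alone, moderation with trend and robust settings, a minimum change, the set of control mice, other score genes, and leaving out the array with contradictory labels or the arrays of a different array run. Covariates for pancreas markers and for Actb, a term for the array run, and leaving out either of the arrays of lowest weight were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.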

Results

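Gene expression was measured in the colon of 72 mice with Affymetrix 3 prime expression arrays, 1 array per mouse. Acute colitis had been induced in 64 of them by rectal trinitrobenzene sulfonic acid (TNBS), a hapten given in ethanol that provokes an intense inflammation of the colon, at 70 µg per g body weight, and the colon was taken on day 4. The colitic mice were left untreated (n = 8) or received, before TNBS, a control antibody against human CD20 at 10 mg/kg (n = 15), TNFR-Ig at 0.3 mg/kg (n = 12), an antibody against TWEAK at 10 mg/kg (n = 14), or the combination of TNFR-Ig and anti-TWEAK at these doses (n = 15). TNFR-Ig is a soluble fusion protein of a TNF receptor that binds the cytokine TNF. TWEAK is a cytokine of the TNF family whose receptor, Fn14, is encoded by Tnfrsf12a. TNFR-Ig mice received no control antibody. The remaining 8 mice were naive. The labels place 34 arrays in experiment 7 and 38 in experiment 10, and naive mice were in experiment 10 alone. The number of mice the study states for each colitic group equals its number of arrays. Array number limits the precision of every value, and 37.5% of values lay within 0.1 log2 units of the floor of the table. Tests were made on 12534 genes with limma, with the experiment as a term of the model, and changes are given as log2 differences with their standard error (SE). Adjusted p-values (adj. p) follow Benjamini and Hochberg.

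The comparison of untreated TNBS with naive mice asked what colitis changed in the colon. Genes of neutrophils and of inflammatory signalling showed the largest rises. S100a8, a subunit of the antimicrobial protein calprotectin, rose by 9.77 ± 0.72 (SE, 871-fold; n = 8 and 8), a fitted change that allows for the experiment; the unadjusted mean log2 levels were 4.45 ± 2.1 (SD) in naive and 14.61 ± 0.45 in untreated mice. Il1b, the cytokine interleukin 1 beta, rose 650-fold (9.35 ± 0.75), and Clec4d, a lectin receptor of myeloid cells, rose 958-fold (9.90 ± 0.60). The neutrophil-attracting chemokine genes Cxcl2 and Cxcl3 rose 554-fold and 344-fold, the chemokine gene Ccl3 412-fold, the macrophage lectin gene Chil3 520-fold, and Lcn2, which sequesters bacterial iron carriers, 331-fold. At the other end, Dbp, a transcription factor of the circadian clock, fell by 4.19 (SE 0.32), Mylk4, a kinase of muscle, by 4.18 (SE 1.11), and Grin3a, a glutamate receptor subunit, was at -4.08 ± 0.65. For Dbp another hour of killing cannot be told apart from colitis, as the hour is not given. Genes of hair keratin-associated proteins made up much of the largest falls: Krtap16-3, Krtap8-1, Krtap22-2 and Krtap19-5 had mean log2 levels of 7.78, 7.27, 6.95 and 6.52 in naive mice and lay at the floor of the table on 7 of 8 untreated arrays each. Their fitted changes, between -5.33 and -4.30, therefore depend on the floor. In the same way the fold of a rise depends on the floor where naive arrays lay at it, as for Cxcl3 (7 of 8 arrays), Clec4d and Ccl3 (4 of 8 each).

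All 12 measured neutrophil markers rose in colitis, with a median change of 6.38. Among them were Stfa2l1 (8.35 ± 1.01) and Fpr2, a formyl peptide receptor (8.08 ± 0.84); for this list adj. p = 6.5e-10 with a preset correlation between genes and adjusted p = 0.113 with an estimated correlation. All 21 monocyte and macrophage markers rose too, among them Arg1, an arginine-degrading enzyme (5.71 ± 0.64), and Fcgr1, an antibody receptor (18.3-fold, SE 0.35 log2 units), and this list passed with the estimated correlation as well (adjusted p = 0.0432 with an estimated correlation). Of 17 matrix proteases and their inhibitors 15 rose and 0 fell, led by the inhibitor gene Timp1 (8.12 ± 0.65) and the protease genes Mmp9 (7.15 ± 0.51) and Mmp3 (7.03 ± 0.60; adjusted p = 0.0399 with an estimated correlation for the list). Among 23 cytokines and chemokines 17 rose and 1 fell (adjusted p = 0.113 with an estimated correlation). The canonical NF-kB target list, genes induced by the transcription factor NF-kB, had 19 of 32 members higher and 3 lower, with Cxcl5 at 7.44 ± 0.45 (adjusted p = 0.122 with an estimated correlation). Endothelial markers rose in 11 of 14 cases and fell in 1, for example Cdh5, the adhesion protein of vessel walls (1.64 ± 0.22). Of 20 genes of matrix and fibroblasts 16 rose and 2 fell, with Lox, which cross-links collagen, at 3.23 ± 0.31. Their adjusted p was 0.19 with an estimated correlation for the endothelial list and 0.17 for the matrix list. Both measured platelet genes of the blood cell list rose, Ppbp by 3.61 ± 0.53 and Pf4 by 1.44 ± 0.18 (adjusted p = 0.113 with an estimated correlation).

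Markers of differentiated colonocytes, the absorptive cells of the colon, moved the other way: 20 of 24 fell and 2 rose, with the water channel gene Aqp8 at -1.47 ± 0.23 and the bile acid transporter gene Slc51a at -1.29 ± 0.45 (adjusted p = 0.122 with an estimated correlation). All 14 smooth muscle markers fell, among them Pln, which restrains the calcium pump (-1.67 ± 0.41), and Casq2, a calcium store protein (-1.50 ± 0.35; adjusted p = 0.234 with an estimated correlation). All 3 measured tuft cell markers fell, with the ion channel gene Trpm5 at -2.12 ± 0.29 (adjusted p = 0.0705 with an estimated correlation). Interferon-stimulated genes fell in 11 of 23 cases and rose in 0, Ifit3 by 2.02 (SE 0.47) and Irf7 by 1.68 (SE 0.42); the list itself did not pass (adj. p = 0.0567). Cell cycle genes rose in 8 of 25 cases, with the replication helicase gene Mcm5 at 0.80 ± 0.21 (adjusted p = 0.748 with an estimated correlation). Goblet cell markers rose in 5 and fell in 2 of 16 cases, enteroendocrine markers rose in 2 and fell in 6 of 12, neuron and glia markers rose in 1 and fell in 5 of 11, and stem cell markers rose in 3 and fell in 4 of 13. Fatty acid oxidation genes rose in 1 and fell in 5 of 20 cases, adipocyte markers fell in 2 of 8, and oxidative phosphorylation genes rose in 1 and fell in 2 of 24. T cell and B cell markers each rose in 1 and fell in 1 case, of 12 and of 10, dendritic cell markers fell in 1 of 8, and mast cell markers rose in 2 and fell in 1 of 3. The only eosinophil marker measured, Siglecf, fell by 0.90 (SE 0.22). Epithelial injury genes rose in 6 and fell in 3 of 16 cases, with the phospholipase gene Pla2g2a at 3.53 ± 0.43. None of these lists passed as a list (adj. p of at least 0.177). Markers of the exocrine pancreas and of skeletal muscle fell in 1 case each, of 9 and of 10, and 0 of 11 squamous epithelium markers passed. Adjusted over the list alone, 12 neutrophil, 21 macrophage, 15 protease and 20 NF-kB genes rose, and 21 colonocyte and 14 smooth muscle genes fell.

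Among the genes of the pathways the treatments target, Tnfrsf12a rose 2.82-fold (SE 0.26 log2 units, adj. p = 2.04e-06), the TNF receptor genes Tnfrsf1b and Tnfrsf1a by 1.30 ± 0.15 and 0.66 ± 0.12, the NF-kB inhibitor gene Nfkbia by 0.36 ± 0.078 and the NF-kB subunit gene Rela by 0.21 ± 0.058. Relb was at -0.24 ± 0.12 (adj. p = 0.102). Nfkb2 fell by 0.32 (SE 0.094) on the brightest probe set and was 0.56 higher on its other probe set. Tnf was left out as dim: it lay at the floor on 8 of 8 naive arrays and on 5 of 8 untreated arrays, and its mean log2 level was between 2.10 (naive) and 2.48 (anti-TWEAK) in all groups. Over all genes, 5989 of 12534 passed at an adjusted p of 0.05, 2785 higher and 3204 lower in colitis, and 913 of them changed by at least 1 log2 unit (569 higher, 344 lower). Within experiment 10 alone, which holds all naive mice, 6005 genes passed. The preset correlation called 12 lists in all, and the estimated correlation called 2 of them, the macrophage and the protease list.

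The control antibody was compared with no treatment to learn whether an antibody alone moved expression in colitis. Of 21 macrophage markers 15 fell with the antibody and 0 rose, among them the integrin gene Itgam (-1.50 ± 0.31), Adgre1, which encodes the macrophage antigen F4/80 (-1.15 ± 0.23), and the lysosomal protein gene Cd68 (-1.14 ± 0.29; n = 15 and 8). For this list adj. p = 1.46e-17 with the preset correlation and adjusted p = 0.134 with an estimated correlation. Interferon-stimulated genes rose in 12 of 23 cases and fell in 0, such as the GTPase genes Iigp1 (1.21 ± 0.41) and Igtp (0.98 ± 0.31; adjusted p = 0.328 with an estimated correlation). The largest rises were those of Akr1c21, a steroid dehydrogenase (2.06 ± 0.42), the interferon-induced chemokine Cxcl9 (1.82 ± 0.59), and Ido1, which degrades tryptophan (1.51 ± 0.46). Gbp8, Lgals2, Abcg5 and Pax8 followed at 1.46, 1.41, 1.27 and 1.22. The largest falls were those of Ngp, a granule protein of neutrophils (31.9-fold, SE 1.12 log2 units), Marco, a scavenger receptor (-3.75 ± 0.93), Cyp1b1, a cytochrome enzyme (-3.72 ± 0.91), the carboxylate transporter gene Slc13a3 (-3.59 ± 0.89), the collagenase gene Mmp8 (-3.16 ± 1.08) and the cytokine gene Tnfsf11 (-2.65 ± 0.55). Ifitm6 and Prok2 were at -2.53 and -2.45.

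Endothelial markers fell in 6 of 14 cases, for example the clotting factor gene Vwf (-0.63 ± 0.16), and matrix genes in 7 of 20, for example Lox (-0.78 ± 0.26); adjusted p = 0.201 and 0.245 with an estimated correlation. Neutrophil markers fell in 4 of 12 cases (adjusted p = 0.328 with an estimated correlation), proteases in 4 of 17 (0.328), NF-kB targets in 4 of 32 with 1 rise (0.465), and the non-canonical NF-kB list in 3 of 8 (0.0586). Dendritic cell markers rose in 1 of 8 cases, Irf8 at 0.35 ± 0.083, and in 7 of 8 when adjusted over the list alone. In the same way 18 macrophage and 11 matrix genes fell and 15 interferon-stimulated genes rose when adjusted over the list alone. Tnfrsf12a (0.10 ± 0.22, adj. p = 0.794), Tnfrsf1a (-0.21 ± 0.099, adj. p = 0.157) and Tnfrsf1b (-0.19 ± 0.13, adj. p = 0.353) did not pass, and neither did Nfkb2, Rela, Relb or Nfkbia. In all, 1296 genes passed, 604 higher and 692 lower with the antibody, and 135 of them changed by at least 1 log2 unit, 13 higher and 122 lower. Within experiment 7 (8 and 4 mice) 6 genes passed, all lower, and within experiment 10 (7 and 4 mice) 2237, 1596 higher and 641 lower, and a fit of these groups alone called 711. Of the 31 lists 12 passed with the preset correlation and 0 with the estimated correlation.

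TNFR-Ig alone, at its low dose, was set against the control antibody. These groups differ by TNFR-Ig and by the 10 mg/kg of control antibody, so the comparison holds the change of the antibody with its sign turned. With untreated mice as the control, an alternative added after the values were seen, 377 genes passed, 62 of them among the 512 that passed against the control antibody; Cyp1b1 was then at -0.72, Akr1c21 at 0.78, Adgre1 at -0.49 and Vwf at 0.0059. Against the control antibody the changes were small: of the 512 genes that passed, 295 higher and 217 lower, 10 changed by at least 1 log2 unit. The balance of directions depended on the test: with every probe set 351 were higher and 402 lower, and with untreated mice as the control 296 were higher and 81 lower. Cyp1b1 rose 8.01-fold (SE 0.80 log2 units; n = 12 and 15), Prg4, the joint lubricant lubricin, by 1.74 ± 0.49, the glycosyltransferase gene Galnt15 by 1.56 ± 0.46 and the lipid droplet gene Plin4 by 1.34 ± 0.39. Fam107a, Angptl4 and Klf15, genes that glucocorticoids are known to induce, each rose by 1.08 (SE 0.31, 0.30 and 0.31), and Zc3h6 by 0.99 ± 0.16. Akr1c21 fell by 1.28 (SE 0.37), the lipid transporter gene Mfsd2a by 1.04 (SE 0.25), and the heat-shock genes Hspa1a and Hspa1b by 0.73 (SE 0.22) and 0.54 (SE 0.11). Rad51c, a DNA repair gene, Exog, a mitochondrial nuclease, Suv39h2, a histone methyltransferase, and Tubd1, a tubulin, fell by 0.67, 0.61, 0.54 and 0.49.

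Macrophage markers rose in 5 of 21 cases and fell in 0, with Adgre1 at 0.67 ± 0.21 and Csf1r, the receptor of a macrophage growth factor, at 0.49 ± 0.12 (list adj. p = 3.7e-07; adjusted p = 0.736 with an estimated correlation). Endothelial markers rose in 3 of 14 cases, Vwf by 0.64 ± 0.14 and Lyve1, a marker of lymph vessels, by 0.50 ± 0.14 (adjusted p = 0.727 with an estimated correlation). Adjusted over the list alone these counts were 9 and 11. Of the 32 NF-kB targets 1 rose, Tnip1, a brake on NF-kB signalling (0.29 ± 0.070), and 0 fell. Among 23 cytokines and 12 neutrophil markers 0 passed, with medians of 0.12 and 0.55. Tnfrsf12a was at -0.40 ± 0.19 (adj. p = 0.219), Tnfrsf1a at 0.14 ± 0.088 (adj. p = 0.347) and Tnfrsf1b at 0.012 ± 0.12 (adj. p = 0.966). Rela (0.075 ± 0.044), Relb (0.15 ± 0.092), Nfkb2 (0.044 ± 0.071) and Nfkbia (0.093 ± 0.059) did not pass. Within experiment 7 limma called 0 genes and within experiment 10 it called 1950, 1048 higher and 902 lower, and without the array of TNFR-Ig replicate 1 of experiment 7, which had the second lowest array weight (0.386) and was left out after its values were seen, 328 genes passed. The preset correlation called 9 of the 31 lists, and the estimated correlation called 0.

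Anti-TWEAK alone changed 351 genes against the control antibody, 143 higher and 208 lower, mostly by small amounts (median absolute change 0.20 among them). The zinc finger gene Zc3h6 rose by 0.95 ± 0.16 (1.93-fold; n = 14 and 15) and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, by 0.93 ± 0.20. The lipid transporter gene Abca8a rose by 0.73 ± 0.21, Fam189a1 by 0.66 ± 0.17, the flavin monooxygenase gene Fmo2 by 0.65 ± 0.18, Ypel4 by 0.65 ± 0.13, the glial cadherin gene Cdh19 by 0.62 ± 0.17 and the mitochondrial carrier gene Slc25a53 by 0.58 ± 0.11. Hspa1a fell by 0.94 (SE 0.21) and Hspa1b by 0.63 (SE 0.11), Gad2, a GABA-producing enzyme, by 0.82 (SE 0.24), Fam72a by 0.79 (SE 0.18), Zbtb40 by 0.64 (SE 0.13) and Thap2, Suv39h2 and Exog by 0.55, 0.54 and 0.54. Of the 430 list members measured 1 passed, the kallikrein gene Klk1 of goblet cells (0.080 ± 0.021). NF-kB targets had a median of 0.048, cytokines of -0.25 and neutrophil markers of -0.18, with 0 members past the threshold in each. With limma's camera test 0 of 31 lists passed with either correlation. Tnfrsf12a was at -0.28 ± 0.18 (adj. p = 0.467), Tnfrsf1b at -0.11 ± 0.11 (adj. p = 0.658) and Tnfrsf1a at 0.042 ± 0.084 (adj. p = 0.851), and Rela, Relb, Nfkb2 and Nfkbia did not pass. Within experiment 7 limma called 0 genes, within experiment 10 it called 1873, 1160 higher and 713 lower, with pooled controls 182 were higher and 146 lower, and across both experiments 2099 genes had an unadjusted p under 0.05. With quantile normalization the share of higher genes went from 40.7% to 53.2%.

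With the combination more genes passed against the control antibody, 3908 in all, 1777 higher and 2131 lower (n = 15 and 15). With pooled controls 2126 were higher and 1997 lower. Within experiment 10 the counts were close, 1950 for TNFR-Ig, 1873 for anti-TWEAK and 2200 for the combination. Within experiment 7 they were 0, 0 and 1059. Such counts do not test whether effects differ in size, and the direct comparison with anti-TWEAK called 0 genes. A measure of RNA degradation was higher, and RNA quality thus lower, for combination mice in experiment 10. The 3 prime minus 5 prime difference was 1.24 ± 0.13 (SD) for Actb in combination mice and 1.11 ± 0.068 in control antibody mice (n = 7 and 7), and 0.844 and 0.759 for Gapdh. For Actb it was 1.16 in TNFR-Ig and 1.18 in anti-TWEAK mice of that experiment. With Actb as a covariate, added after the values were seen, 3475 genes passed for the combination, 1436 higher and 2039 lower. Without combination replicate 7 of experiment 7, which had the lowest array weight (0.201) and the lowest median correlation with the other arrays (0.987), 3451 passed, an alternative added after the values were seen. Clec4e, a receptor for fungal and mycobacterial glycolipids on myeloid cells, fell 10.5-fold (SE 0.79 log2 units), Acod1, which makes the antimicrobial metabolite itaconate, fell by 3.28 (SE 0.78), Ccl3 by 3.27 (SE 0.82), Hdc, the enzyme that makes histamine, by 3.19 (SE 0.74) and Il1r2, a decoy receptor of interleukin 1, by 2.65 (SE 0.64). Stfa2l1, Cxcl3 and Chil3 fell by 2.76, 2.67 and 2.56. Il1b fell by 2.31 (SE 0.53, 4.97-fold), from a mean log2 level of 12.68 ± 0.96 (SD) to 10.37 ± 2.25. Itln1, a lectin of intestinal secretory cells, rose by 2.14 ± 0.51, Ang4, an antimicrobial ribonuclease, by 1.96 ± 0.59, the phospholipase gene Pla2g4c by 1.78 ± 0.62 and H2-Ob, which takes part in antigen presentation by B cells, by 1.66 ± 0.41. Genes of the male accessory glands were among the largest rises: Pate14 rose by 4.03 ± 1.16 and Pbsn, the prostate protein probasin, by 3.60 ± 1.41. A list of such genes, chosen after the values were seen, varied widely between mice. Its mean log2 level per mouse ran from 3.88 to 13.7 in combination mice. It reached 10.7 in naive and 10.9 in TNFR-Ig mice, and 6.24 in control antibody mice, so high levels were not particular to the combination. Dcpp3 rose by 3.58 ± 1.25, with 0.65 in experiment 7 (adj. p = 0.875) and 6.93 in experiment 10. Spinkl passed too, but lay at the floor on the control antibody arrays.

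Members of inflammatory lists that passed mostly fell with the combination, while none of these lists passed with an estimated correlation. Of 32 NF-kB targets 14 fell and 3 rose, among them Cxcl1 (-2.02 ± 0.54), Cxcl2 (-2.02 ± 0.58) and Il6, the cytokine interleukin 6 (-1.86 ± 0.72; adjusted p = 0.581 with an estimated correlation). Of 23 cytokines and chemokines 13 fell and 2 rose, and of 12 neutrophil markers 8 fell and 0 rose, with Mmp8 at -2.52 ± 0.90 and Cxcr2, the receptor through which neutrophils are recruited, at -2.37 ± 0.58. Matrix proteases fell in 10 of 17 cases and rose in 1, with Mmp3 at -1.67 ± 0.42, Mmp13 at -1.36 ± 0.34 and Mmp9 at -1.29 ± 0.36. For each of these 3 lists adjusted p = 0.534 with an estimated correlation. Macrophage markers fell in 6 of 21 cases and rose in 0, with Clec4d at -1.48 ± 0.43 and Arg1 at -1.19 ± 0.46. Cell cycle genes fell in 15 of 25 cases and rose in 0, for example Plk1 (-0.53 ± 0.18) and Aurka (-0.52 ± 0.18), kinases of mitosis (adjusted p = 0.534 with an estimated correlation). Epithelial injury genes fell in 4 of 16 cases, Lcn2 by 1.81 (SE 0.62) and Pla2g2a by 1.27 (SE 0.30). Among matrix genes 2 of 20 fell and 1 rose, with Thbs1 at -0.88 ± 0.22. Adjusted over the list alone, 14 NF-kB targets, 16 cytokines, 8 neutrophil markers, 11 proteases and 20 cell cycle genes fell.

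Members of the lymphocyte and dendritic cell lists that passed were higher, while none of these lists passed with an estimated correlation. B cell markers rose in 7 of 10 cases, the surface protein genes Ms4a1 2.83-fold (SE 0.53 log2 units) and Cd79b by 1.30 ± 0.37, T cell markers in 5 of 12, the T cell receptor genes Cd3d by 0.92 ± 0.28 and Cd3g by 0.91 ± 0.29, and dendritic cell markers in 5 of 8, the integrin gene Itgae by 0.76 ± 0.18 and the antigen presentation gene H2-Eb1 by 0.47 ± 0.14. None of these 30 genes fell, and each list had adjusted p = 0.534 with an estimated correlation. The T cell and dendritic cell values were larger in experiment 7: Cd3d was at 1.46 there and at 0.30 in experiment 10, Cd3g at 1.53 and 0.19, and Itgae at 1.00 and 0.49. List medians in experiments 7 and 10 were 0.61 and -0.032 for T cells, 0.56 and 0.12 for dendritic cells and 0.46 and 0.75 for B cells. The difference between the experiments had adj. p = 1.41e-06 for the T cell list with the preset correlation and adjusted p = 0.207 with an estimated correlation. Fatty acid oxidation genes rose in 7 of 20 cases, with the transcription factor gene Ppara at 0.69 ± 0.23 and Cpt1a, the gate of mitochondrial fatty acid import, at 0.22 ± 0.054 (adjusted p = 0.534 with an estimated correlation). All 3 tuft cell markers rose, Trpm5 by 0.61 ± 0.21 (adjusted p = 0.534 with an estimated correlation), colonocyte markers rose in 4 of 24 cases (0 when adjusted over the list alone; adjusted p = 0.534 with an estimated correlation), goblet cell markers in 4 of 16 with 1 fall, and smooth muscle markers in 2 of 14 (adjusted p = 0.585 with an estimated correlation). Enteroendocrine markers rose in 3 of 12 cases and endothelial markers in 2 of 14, and 0 of 11 neuron and glia markers passed. Interferon-stimulated genes fell in 1 of 23 cases, Cxcl10 at -1.08 ± 0.26. The pancreas list had a median of 2.39 with 1 of 9 members passing, Clps, a cofactor of pancreatic lipase (1.03 ± 0.36, list adjusted p = 0.581 with an estimated correlation). Its median was 5.39 in experiment 7 and -1.13 in experiment 10. The mean log2 level of its markers was 4.69 and 9.89 in control antibody mice of these experiments, and 9.53 and 8.89 in combination mice.

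Tnfrsf12a fell by 0.86 (SE 0.18, adj. p = 0.000374) and Tnfrsf1b by 0.53 (SE 0.11, adj. p = 0.000278) under the combination. Tnfrsf1a (-0.13 ± 0.083, adj. p = 0.243), Rela (-0.035 ± 0.041, adj. p = 0.552), Relb (0.16 ± 0.087, adj. p = 0.15) and Nfkbia (-0.11 ± 0.055, adj. p = 0.106) did not pass. Nfkb2 rose by 0.18 ± 0.067 on its brightest probe set and was at -0.25 ± 0.11 on the other. Of the 3908 genes 3872 had the same sign in both experiments, and 133 changed by at least 1 log2 unit (56 higher, 77 lower). Within experiment 7 (8 and 8 mice) 1059 genes passed, 373 higher and 686 lower, and within experiment 10 (7 and 7 mice) 2200, 1251 higher and 949 lower. The preset correlation called 13 of the 31 lists and the estimated correlation called 0.

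**Figure D1:**
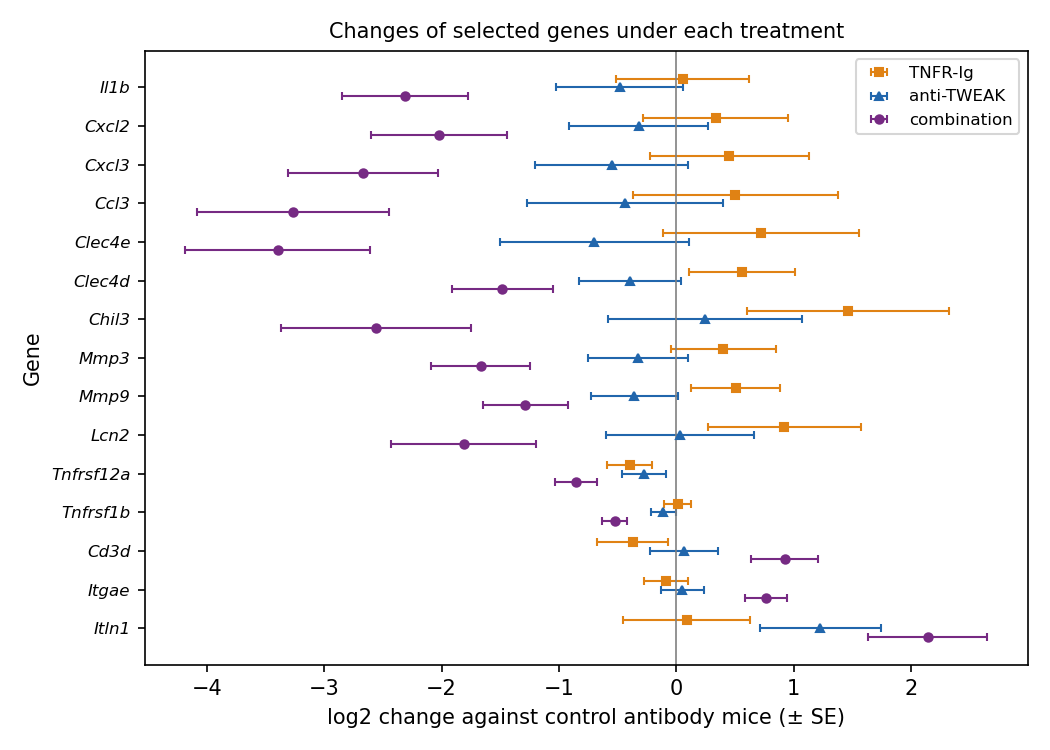
Log2 change against control antibody mice (horizontal axis) of 15 genes that passed in the combination comparison, for TNFR-Ig (squares, n = 12), anti-TWEAK (triangles, n = 14) and the combination (circles, n = 15) against 15 control mice. Points are limma estimates and bars are 1 SE; Il1b, for example, lies at -2.31 under the combination.

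Combination mice were next compared with TNFR-Ig mice, which received neither the anti-TWEAK antibody nor any control antibody, so an effect of 10 mg/kg of any antibody is part of this comparison. With the change of the control antibody against untreated mice subtracted, an alternative added after the values were seen, 654 genes passed, 131 of them among the 841 that passed without it. Mmp8 was then at -1.28, Chil3 at -1.27 and Msr1 at -0.032, much closer to no change. Ccl3 at -3.37, Acod1 at -3.24, Hdc at -3.11 and Il1b at -2.27 (-2.37 without the subtraction) kept most of theirs. None of these passed. Of the genes named for this comparison that passed without the subtraction, Cr2 alone still passed with the same sign (0.97). The subtraction brings in control antibody mice and the 8 untreated mice, which makes it less precise. A gene that no longer passed thus need not have had a smaller change. Mmp8 was lower by 4.44 log2 units with the combination (-4.44 ± 0.95, 21.7-fold; n = 15 and 12), and Clec4e (-4.12 ± 0.84), Chil3 (-4.02 ± 0.86), Acod1 (-3.95 ± 0.83), Hdc (-3.83 ± 0.78) and Ccl3 (-3.77 ± 0.87) fell by similar amounts. Ptx3, a secreted pattern recognition protein, fell by 3.60 (SE 0.82) and Il1r2 by 3.51 (SE 0.68). The largest rises were those of Pbsn (5.37 ± 1.49), Dcpp3 (5.29 ± 1.33, with TNFR-Ig mice at the floor), Pate14 (3.89 ± 1.23) and Mylk4 (2.98 ± 0.83). The defensin gene Defb1 (2.61 ± 0.86), the muscle genes Casq1 (2.26 ± 0.64) and Actc1 (1.68 ± 0.48), and Itln1 (2.05 ± 0.54) followed. In experiments 7 and 10, Mylk4 was at 4.62 and 1.21, Casq1 at 3.6 and 0.83 and Defb1 at 4.5 and 0.65. Pate14 was at 4.94 and 2.72, and Dcpp3 went the other way, at 3.9 and 6.93. Pbsn (5.57 and 5.09), Itln1 (2.18 and 1.93) and Actc1 (1.91 and 1.43) were closer in both. Neutrophil markers fell in 9 of 12 cases, macrophage markers in 13 of 21, with the scavenger receptor gene Msr1 at -1.06 ± 0.25, and proteases in 9 of 17, with Timp1 at -1.85 ± 0.49; none of these members rose. NF-kB targets fell in 15 of 32 cases and rose in 1, with Il6 at -2.43 ± 0.76, and cytokines fell in 12 of 23 and rose in 1. T cell markers rose in 4 of 12 cases, Cd3d by 1.30 ± 0.30, dendritic cell markers in 4 of 8, Itgae by 0.85 ± 0.19, and B cell markers in 3 of 10, with the complement receptor gene Cr2 at 0.76 ± 0.20. For the B cell list adjusted p = 0.189 with an estimated correlation, and for the others named here it was 0.117.

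Endothelial markers fell in 6 of 14 cases, with the receptor gene Tie1 at -0.71 ± 0.19, and matrix genes in 6 of 20, with Lox at -0.84 ± 0.23; adjusted p = 0.196 and 0.29 with an estimated correlation. Interferon-stimulated genes rose in 2 of 23 cases, Ifit3 by 1.09 ± 0.35 and Ifit2 by 0.72 ± 0.22 (adjusted p = 0.29 with an estimated correlation), smooth muscle markers in 2 of 14, Casq2 by 0.93 ± 0.26 (adjusted p = 0.29 with an estimated correlation), and Ascl2, a transcription factor of intestinal stem cells, by 0.89 ± 0.24. Tnfrsf1b fell by 0.54 (SE 0.12), Tnfrsf1a by 0.27 (SE 0.088) and Nfkbia by 0.21 (SE 0.059), whereas Tnfrsf12a (-0.46 ± 0.19, adj. p = 0.131), Rela (-0.11 ± 0.044, adj. p = 0.113) and Relb (0.0071 ± 0.092, adj. p = 0.973) did not pass; Nfkb2 was at 0.13 ± 0.071 and, on its other probe set, at -0.40 ± 0.12. Adjusted over the list alone, 21 NF-kB targets, 11 neutrophil markers, 18 macrophage markers and 17 cytokines fell. In all 841 genes passed, 277 higher and 564 lower with the combination. Within experiment 7 limma called 11 genes and within experiment 10 it called 719, and 496 passed in a fit of these groups alone. The preset correlation called 20 of the 31 lists and the estimated correlation called 0.

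Against anti-TWEAK mice, from which combination mice differ by TNFR-Ig, limma called 0 of 12534 genes, while 2258 had an unadjusted p under 0.05 (n = 15 and 14). The genes with the smallest p were Arntl, a core transcription factor of the circadian clock (-0.66 ± 0.14), Pias3 (0.18 ± 0.039), N4bp1 (-0.23 ± 0.052), Trim7 (0.44 ± 0.10) and Ncoa5 (-0.17 ± 0.038), each with adj. p = 0.0807. Tnfrsf12a was at -0.58 ± 0.18 (adj. p = 0.142), Tnfrsf1b at -0.42 ± 0.11 (adj. p = 0.107), Tnfrsf1a at -0.17 ± 0.084 (adj. p = 0.275) and Nfkbia at -0.17 ± 0.056 (adj. p = 0.146); Rela, Relb and Nfkb2 lay between -0.062 and 0.073. No list member passed over all genes. Adjusted over the list alone, 16 of 32 NF-kB targets were lower and 1 higher, 11 of 12 neutrophil markers and 10 of 23 cytokines were lower, and 6 of 8 dendritic cell markers were higher; for these lists adjusted p = 0.302 with an estimated correlation. The exocrine pancreas list had a median of 2.90, with 0 of 9 members passing (adjusted p = 0.406 with an estimated correlation). Within experiment 7 limma called 61 genes, within experiment 10 it called 0, with array weights 305, and with the mean of the pancreas markers as a covariate, added after the values were seen, 395. The preset correlation called 14 lists and the estimated correlation called 0.

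Departure from additivity was tested as the combination effect minus the sum of both single effects, each against the control antibody. As TNFR-Ig mice received no antibody, this contrast keeps the effect of an antibody once, and if anti-TWEAK shares the effect of the control antibody, additive treatments would depart by the change of control antibody against untreated mice. With untreated mice in place of control antibody mice, an alternative added after the values were seen in which a shared effect cancels, 89 genes passed, 23 above and 66 below the sum, 5 of them among the 40 of the contrast with control antibody mice; Prg4 was then at -0.76, Pappa at -0.92 and Vwf at -0.19. Siglece, an inhibitory receptor of myeloid cells, lay below the sum by the most (-3.34 ± 0.82 log2 units; 56 mice), followed by Prg4 (-2.96 ± 0.68) and Fam107a (-2.02 ± 0.43). Pappa, a protease of growth factor binding proteins (-1.48 ± 0.37), Ms4a6d (-1.38 ± 0.34), the chemokine-binding receptor Ackr1 of venules (-1.36 ± 0.31), the clotting factor F13a1 (-1.35 ± 0.33), Ggt5 (-1.30 ± 0.31) and Vwf (-0.82 ± 0.20) were below it too. Above the sum were Sfmbt1 (0.44 ± 0.10), Hs3st3b1 (0.39 ± 0.083), Mkx (0.27 ± 0.063), Tigar (0.26 ± 0.064), Zfp790 (0.26 ± 0.060), Hopx (0.24 ± 0.061), Tspan13 (0.22 ± 0.052) and Mtmr4 (0.19 ± 0.038). Of the list members 1 passed, Vwf of the endothelial list. Adjusted over the list alone, 16 of 32 NF-kB targets, 11 of 12 neutrophil markers and 17 of 21 macrophage markers were below the sum (medians -0.44, -2.08 and -0.66); for each of these lists adjusted p = 0.164 with an estimated correlation. Tnfrsf12a (-0.18 ± 0.27, adj. p = 0.816), Tnfrsf1b (-0.43 ± 0.16, adj. p = 0.169), Tnfrsf1a (-0.31 ± 0.12, adj. p = 0.194) and Nfkbia (-0.26 ± 0.081, adj. p = 0.0982) did not pass, nor did Rela, Relb or Nfkb2. In all 40 genes passed, 10 above and 30 below the sum, and this count did not hold: limma called 0 genes without the experiment term or within experiment 7, 461 within experiment 10, 5 without TNFR-Ig replicate 1 of experiment 7 and 334 without combination replicate 7 of experiment 7. The preset correlation called 14 lists and the estimated correlation called 0.

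Whether a treatment acted alike in both experiments was tested as a difference of its effects. For TNFR-Ig limma called 0 genes (1301 with an unadjusted p under 0.05; 1 with array weights). For anti-TWEAK it called 215 genes, 167 with a higher effect in experiment 10 and 48 with a lower one. The exocrine pancreas list moved with it by a median of -7.63 (adj. p = 1.25e-06 with the preset correlation, 0.372 with an estimated correlation). For TNFR-Ig it moved by -4.26 and for the combination by -6.94 (adjusted p = 0.421 and 0.207 with an estimated correlation). In the control antibody mice, shared by these tests, the mean of its markers was 4.69 in experiment 7 and 9.89 in experiment 10. It was 7.11 and 5.95 in anti-TWEAK, 7.4 and 9 in TNFR-Ig and 9.53 and 8.89 in combination mice, so much of each shift lies in the control mice. For anti-TWEAK limma called Naaladl1, an intestinal peptidase (-0.91 in experiment 7, 1.30 in experiment 10, adj. p = 0.0325), and the clock repressor Nr1d1 (-0.58 and 1.22, adj. p = 0.0112). It also called Foxc2, a transcription factor of lymph vessels (0.86 and -0.91, adj. p = 0.0342), and Fhod3, an organiser of actin filaments (-0.39 and 1.21, adj. p = 0.0171). These are the 4 largest differences among the genes that passed, predicted genes left out. For the combination it called 4 genes, named here after their values were seen: H3f3b, a histone (1.92 and -0.51), Arntl (-1.31 and -0.068), Lonrf1 (0.57 and -0.15) and Npas2, the partner of clock transcription factors (-0.54 and 0.18). Without the 2 combination arrays of experiment 7 that were run with experiment 10, an alternative added after the values were seen, it called 21.

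A colitis score summarised each mouse: the mean log2 level of the 569 genes that were higher in colitis minus that of the 344 that were lower, each by at least 1 log2 unit. Naive mice scored -1.95 ± 0.076 (SD, n = 8), untreated TNBS mice 2.20 ± 0.82 (n = 8) and control antibody mice 1.24 ± 0.53 (n = 15). TNFR-Ig mice scored 1.51 ± 0.50 (n = 12), anti-TWEAK mice 1.12 ± 1.13 (n = 14) and combination mice 0.32 ± 0.86 (n = 15). The combination differed from the control antibody by -0.92 (two-sided permutation within experiments, p = 0.00214, adjusted over the 3 treatments 0.00642), which is 28.8% of the distance from control antibody to naive mice, and 12 of 15 combination mice lay below the control mean. Within experiment 7 this difference was -0.83 (exact p = 0.0448, adjusted permutation p = 0.133). Within experiment 10 it was -1.02 (exact p = 0.021, adjusted permutation p = 0.0539). These adjusted values do not derive from the exact p values printed beside them. Neither experiment passed alone after adjustment. TNFR-Ig differed by 0.27 (permutation p = 0.202, adjusted 0.303; exact p = 0.477 and 0.247 within the experiments, where it was 0.24 and 0.29), and 4 of 12 mice lay below the control mean. Anti-TWEAK differed by -0.14 (permutation p = 0.647), with 0.40 in experiment 7 (exact p = 0.384, adjusted permutation p = 0.477) and -0.82 in experiment 10 (exact p = 0.0355, adjusted permutation p = 0.0539, which did not pass). The difference between the experiments was -1.22 (permutation p = 0.0393, adjusted over the 3 treatments 0.118). With untreated mice as the control in place of control antibody mice, the TNFR-Ig difference turned to -0.69 (permutation, adjusted p = 0.0391) and that of anti-TWEAK was -1.13 (adjusted p = 0.0324), although untreated mice had served to choose the score genes. Untreated mice received no antibody, so the anti-TWEAK value holds any effect of an antibody as well. In tests added after these, the combination lay 1.19 below TNFR-Ig (-1.19, permutation p = 0.00052, adjusted 0.00156; -1.08 and -1.30 in experiments 7 and 10), but with the change of the control antibody subtracted the difference was -0.23 (permutation p = 0.565, 50 mice). It lay 0.77 below anti-TWEAK (-0.77, permutation p = 0.0396, adjusted 0.0396; -1.23 and -0.20). Control antibody mice lay 0.95 below untreated mice (-0.95, permutation p = 0.00415, adjusted 0.00622). As the score genes were chosen with untreated mice, this difference may be overstated, here and wherever it serves as the change of the antibody. The departure of the score from additivity was -1.06 (permutation p = 0.0137, 56 mice). It was -1.48 in experiment 7 (permutation p = 0.0228, 30 mice) and -0.48 in experiment 10 (permutation p = 0.33, 26 mice), and the difference between the experiments did not pass (permutation p = 0.204). This departure holds the effect of an antibody once where both antibodies share it, and the control antibody change was itself -0.95. With untreated mice in place of control antibody mice it was -0.094 (permutation p = 0.848, 49 mice), although the score genes were chosen with untreated mice.

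**Figure D2:**
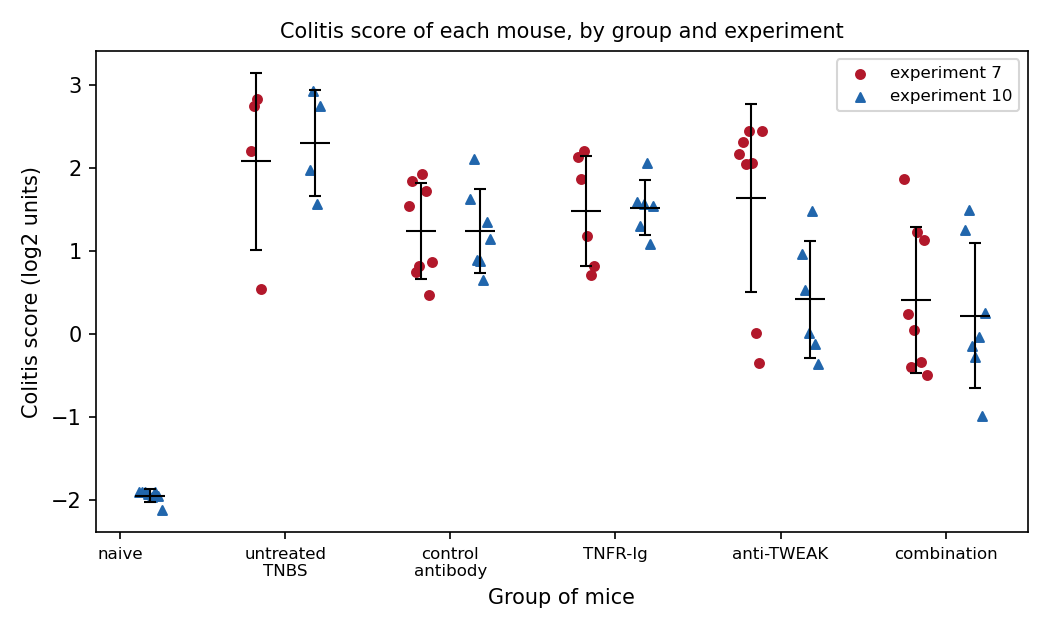
Colitis score of each mouse in log2 units (vertical axis) by group (horizontal axis), with circles for experiment 7 and triangles for experiment 10; black lines are the mean and 1 SD of each group within an experiment. Naive mice sit near -1.95, untreated mice average 2.20 and combination mice 0.32.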

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

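The tests of explanations for the 3 patterns weighed here were chosen after the result was seen, and the pancreas test was changed from a count of genes to a share of the effect after its count had been seen; the tests between experiments and of single arrays were planned.

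The effect of anti-TWEAK differed between the experiments in 215 genes, and the colitis score difference changed by -1.22 from experiment 7 to experiment 10 (permutation p = 0.0393, adjusted 0.118). With Actb as a covariate for RNA quality, a median of 93% of each gene's difference was left (quartiles 89.1% and 97.5%), and with the mean of the pancreas markers, a measure of RNA from the pancreas, 87.3% (quartiles 79.7% and 96%). These shares argue against either as the whole cause, but most calls ended: 85 genes passed with Actb, 82 of them among the 215, and 21 with the pancreas markers, all 21 among the 215, a count that taken alone would favour the pancreas explanation. With the pancreas markers the median absolute difference went from 0.454 to 0.392 and the median SE from 0.112 to 0.116, so calls ended because differences shrank while the error grew slightly. As 0 arrays of experiment 7 from these groups were in array run 2, the array run and the experiment cannot be told apart, and a biological difference between the experiments stays open and untested.

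Heat-shock chaperone genes, chosen after their changes were seen in the same mice, were lower than in control antibody mice by a mean log2 difference of -0.217 with TNFR-Ig (SE 0.0463), -0.222 with anti-TWEAK (SE 0.0374) and -0.361 with the combination (SE 0.0391). Against untreated mice the combination was lower too, at -0.248 (SE 0.0671). As the genes were chosen in the same combination mice, this value may be overstated. It cannot decide whether the control antibody group stands apart. For TNFR-Ig at -0.104 (SE 0.0732) and anti-TWEAK at -0.115 (SE 0.0594) the same question stays open, as the values lie between those of no difference and the full difference. With RNA quality as a covariate the differences from control antibody mice were -0.228, -0.218 and -0.363, and with severity of colitis, as the score, -0.219, -0.216 and -0.326. Most of each difference was thus left, which argues against either as the whole cause. No p is given for these values, as the genes were chosen in the same mice. An effect of the combination is a candidate explanation for its part, found and tested on the same mice.

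Clock genes differed between combination and control antibody mice of experiment 7, with an index of opposing clock genes 1.85 higher in combination mice (SE 0.3); these genes were chosen after their changes were seen in the same mice, so no p is given for the pattern itself. It was 1.38 higher with severity of colitis as a covariate and 1.85 higher among the 6 and 8 arrays of array run 1 alone. Most of the difference was thus left, which argues against either as the whole cause. No p is given for these values either, for the same reason. All 15 clock genes tested moved in the directions that another hour of killing would give; the hour is not given in the sources used here, so it cannot be told apart from the treatment. In experiment 10 the index was 0.71 higher.

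The effect of the combination differed between the experiments in 4 genes. Single arrays far from the rest of their group were sought only among naive and untreated mice, since the other groups hold more than 10 arrays, and were found in 6 of 68 tests, where chance gives about 1 in 20. Of all arrays, combination replicate 7 of experiment 7 had the lowest weight (0.201). The gap to the nearest other array, as a share of the range, was 0.717 for the colitis score of naive replicate 8 (-2.13 against -1.96), 0.66 for the Actb measure of naive replicate 2 (1 against 1.1), and 0.588 for skeletal muscle markers of naive replicate 1 (5.26 against 7.58). It was 0.633 for macrophage markers of untreated replicate 5 of experiment 7 (9.4 against 10.3), 0.724 for B cell markers of untreated replicate 1 of experiment 10 (9.16 against 7.49), and 0.54 for the eosinophil marker of untreated replicate 2 of experiment 10 (4.38 against 5.18).

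Group labels of the compared arrays were redrawn 99 times to learn whether chance alone gives as many genes, within experiments except for colitis, where the labels of the 16 arrays were redrawn without regard to experiment. For colitis (5989 genes, highest other 3370) and control antibody against untreated (1296, highest other 2), 1 of 100 splits was as large, the real one included. That is the smallest share 99 redraws can give. It argues against chance for each comparison taken alone, without allowance for the other comparisons redrawn. The same holds for TNFR-Ig (512, highest other 53), anti-TWEAK (351, highest other 66) and the combination (3908, highest other 111). For the anti-TWEAK difference between experiments (215, highest other 32) it was 1 of 100 too. There redrawn labels also remove the effect of the treatment itself, so this count does not test whether the effects were equal. For the combination against TNFR-Ig (841, highest other 858) and departure from additivity (40, highest other 1371) 2 of 100 splits were as large. For the combination against TNFR-Ig this count alone would argue against chance, again without allowance for the other comparisons redrawn. For additivity it cannot, since redrawn labels also remove the effects of the single treatments, so that additivity itself is not tested. The 40 genes carry little weight, since alternatives called between 0 and 959 and the contrast keeps the effect of an antibody. Chance cannot be excluded for the difference between experiments of the combination (4, highest other 3233; 5 of 100). For the combination against anti-TWEAK (0, highest other 1719) and the difference between experiments of TNFR-Ig (0, highest other 1027) limma called 0 genes, against 2258 and 1301 with an unadjusted p under 0.05. There 100 of 100 splits give as many by construction, which says nothing about chance. Redrawn splits that called far more genes than the real one may reflect a structure of the samples, which was not tested; most were single splits, with a second highest of 1 for additivity, 31 and 59 for the differences between experiments of TNFR-Ig and the combination, and 1278 for the combination against anti-TWEAK.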

How the results depend on the processing

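Alternatives with the array run, the pancreas markers, Actb or without TNFR-Ig replicate 1 or combination replicate 7 of experiment 7 were added after the result was seen, as were those that cancel an antibody effect, the split of the score's additivity by experiment and leaving out 2 arrays for the difference between experiments. Of 172 alternative values of the main results 104 stayed within 1.5 times the count or on the same side of the threshold, and 68 did not; the cause was not tested except where named.

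A minimum change of 1 log2 unit, stricter by construction, left 913 genes for colitis, 135 for control antibody against untreated, 10 for TNFR-Ig, 1 for anti-TWEAK, 133 for the combination, 163 for the combination against TNFR-Ig and 10 for additivity. The estimated correlation left 2 lists for colitis and 0 for control antibody, TNFR-Ig, the combination, both combination contrasts and additivity. Experiment 7 alone gave 6 genes for control antibody, 0 for TNFR-Ig, 0 for anti-TWEAK, 1059 for the combination, 11 and 61 against TNFR-Ig and anti-TWEAK, and 0 for additivity. Experiment 10 alone gave 2237, 1950, 1873 and 2200 for control antibody and the 3 treatments, and 461 for additivity.

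Array weights gave 1947 genes for control antibody, 891 for TNFR-Ig, 903 for anti-TWEAK, 2218 and 305 for the combination against each single treatment, 959 for additivity, and 1, 2189 and 63 for the differences between experiments. No experiment term gave 316 for TNFR-Ig, 203 for anti-TWEAK and 0 for additivity. Fitting only the compared groups gave 711 for control antibody, 496 for the combination against TNFR-Ig and 4 for additivity. Every probe set gave 625 for anti-TWEAK, 2 for the combination against anti-TWEAK and 2 for additivity; no filter gave 1 for additivity. Without the 2 combination arrays of run 2, additivity had 221 genes and the difference between experiments 21. The array run as a term gave 0 for additivity. Pancreas markers as a covariate gave 395 for the combination against anti-TWEAK and 246 for additivity, and Actb gave 1 for the former. Without TNFR-Ig replicate 1 of experiment 7, TNFR-Ig had 328 genes and additivity 5; without combination replicate 7 of experiment 7 additivity had 334.

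A replicate block gave 824 genes for control antibody, 215 for anti-TWEAK, 552 and 7 for the combination against each single treatment, and 0 for additivity. Replicate numbers do not pair the mice: 48 of 132 same-number pairs had a correlation over 0.1, with a mean of -0.00606, and 8 of 72 arrays matched their own number best.

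With untreated mice as the control, the score difference of TNFR-Ig was -0.689, reversed (adjusted permutation p = 0.0391), and that of anti-TWEAK -1.13 (adjusted permutation p = 0.0324). Untreated mice had served to choose the score genes, so both differences may be overstated. The anti-TWEAK value also holds any effect of an antibody, as untreated mice received none. Against the control antibody, anti-TWEAK was at 0.402 in experiment 7 alone, reversed. The combination missed the threshold within each experiment, at -0.833 (adjusted permutation p = 0.133) and -1.02 (adjusted permutation p = 0.0539). For the 92 genes named in the combination comparison 1264 of 1564 alternative values stayed on the same side, 293 no longer passed and 1 reversed, where a gene with several probe sets was judged by that with the smallest p. Smaller shares stayed for control antibody (694 of 882), TNFR-Ig (413 of 595, 25 reversed), the combination against TNFR-Ig (898 of 1206) and additivity (250 of 432). Larger shares stayed for colitis (1401 of 1470), anti-TWEAK (293 of 360) and the combination against anti-TWEAK (165 of 192). Tnf, at the floor on most arrays, shows what low signal limits.

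With untreated mice in place of control antibody mice, additivity had 89 genes, and the score's departure from it was -0.0942 (permutation p = 0.848). In experiment 10 alone the departure with control antibody mice was -0.483. With the control antibody change subtracted, the score difference of the combination against TNFR-Ig was -0.229 (permutation p = 0.565), and Cd163, Vwf and Pf4 reversed to 0.059, 0.14 and 0.31. A departure of the score beyond the effect of an antibody was therefore not shown.

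With untreated mice as the control, these genes named for TNFR-Ig reversed: Cyp1b1 to -0.72, Prg4 -0.46, Angptl4 -0.52, Akr1c21 0.78, Adgre1 -0.49, Csf1r -0.032, C1qc -0.19, C1qb -0.19, Cdca7 0.071, Lyve1 -0.038, Plvap -0.080, Pdgfrb -0.015, Pdgfra -0.00024, Timp2 -0.053, Tnfrsf1a -0.067, Tnfrsf1b -0.18, Nfkb2 -0.059, Rela -0.012 and Nfkbia -0.038. Other reversals were of pathway genes, mostly ones that did not pass. With every probe set Nfkb2 was at 0.56 in colitis and at -0.40, -0.35 and -0.49 for the combination against TNFR-Ig, against anti-TWEAK and for additivity. In experiment 7 alone, Nfkbia went to 0.011 for control antibody; Tnfrsf1b, Nfkb2, Relb and Nfkbia to -0.037, -0.014, -0.054 and -0.0074 for TNFR-Ig and 0.067, -0.013, -0.13 and -0.00082 for anti-TWEAK, and Relb to 0.30 for additivity. In experiment 10 alone, Tnfrsf1a went to -0.012 for anti-TWEAK, Rela to 0.019 for the combination, Relb to -0.16 and -0.15 against TNFR-Ig and anti-TWEAK, and Tnfrsf12a and Nfkb2 to 0.30 and -0.092 for additivity. Pooled controls gave Tnfrsf1b -0.053 for TNFR-Ig, and Tnfrsf1a -0.031 and Rela -0.0035 for anti-TWEAK. Array weights gave Tnfrsf12a -0.014 for control antibody and Relb -0.033 and -0.031 against each single treatment. Without the 2 arrays of run 2 Relb was at -0.095 and -0.032 against each, without combination replicate 7 of experiment 7 at -0.066 and -0.0016, and against TNFR-Ig at -0.022 with the array run and -0.0021 with Actb. Pancreas markers gave Tnfrsf1b -0.0048 for TNFR-Ig, and leaving out TNFR-Ig replicate 1 of experiment 7 gave Nfkb2 -0.019 for additivity.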

Other observations

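Circadian clock genes were among the larger differences between untreated TNBS and naive mice. The hour of killing is not given in the sources used here, so it cannot be told apart from colitis or from a treatment. Of 10 genes of the negative limb and output of the clock 8 fell in untreated against naive mice, Dbp at -4.19 ± 0.32 (SE), Ciart at -3.69 ± 0.36 and the repressor gene Nr1d1 at -3.25 ± 0.32, while Arntl of the positive limb rose by 1.07 (SE 0.192; n = 8 and 8). Under the combination 8 of these 10 rose against the control antibody, Dbp by 1.43 (SE 0.23; 1.51 in experiment 7 and 1.35 in experiment 10) and Ciart by 1.12 (SE 0.255; 2.03 and 0.085), and 4 of 5 positive-limb genes fell (n = 15 and 15). Arntl was at -0.73 ± 0.14 over both experiments, but at -1.31 in experiment 7 and -0.068 in experiment 10, a difference that passed (limma, adjusted p = 0.000964). Npas2, at -0.54 and 0.18, turned sign between the experiments (adjusted p = 0.00522). Heat-shock chaperone genes, which help proteins fold, fell in 9 of 19 cases with TNFR-Ig, 8 with anti-TWEAK and 15 with the combination; Hspa1b fell by 0.54, 0.63 and 0.66, and Hsph1 by 0.37, 0.35 and 0.67.

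Genes that glucocorticoids induce were higher in 15 of 15 cases with TNFR-Ig than with the control antibody, 6 of which passed. Their mean log2 level was 11.80 in untreated, 11.45 in control antibody and 11.86 in TNFR-Ig mice, so this difference cannot be assigned to TNFR-Ig rather than to the antibody that TNFR-Ig mice did not receive. Of the 15, 9 fell in combination against TNFR-Ig mice, which differ by an antibody as well: Zbtb16 by 1.37 (SE 0.227), Fkbp5 by 0.70 (SE 0.16) and Tsc22d3 by 0.44 (SE 0.108). Endoplasmic reticulum chaperones fell in 9 of 16 cases with the combination, Hspa5 by 0.24 (SE 0.0416). Male accessory gland genes rose in 7 of 11 cases, with a mean log2 level of 8.51 ± 3.85 (SD, n = 8) in combination mice of experiment 7 and 4.50 ± 0.61 in their controls (n = 8), but 5.43 and 4.82 in experiment 10 (n = 7 and 7). Levels were also spread widely in naive mice (5.47 ± 2.32, n = 8) and TNFR-Ig mice (5.59 ± 2.56, n = 12). Hair keratin genes were at 6.18 ± 2.35 in naive and 2.17 ± 0.25 in untreated mice (n = 8 and 8).

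All of these lists were chosen after the result was seen, and the hair keratin list partly from names among the largest falls. Adjustment over the list tests does not correct for that choice, so their p-values are likely too small. Over 56 list tests with an estimated correlation, adjusted p in limma's camera was 0.0367, 0.0323 and 0.0323 for heat shock in TNFR-Ig, anti-TWEAK and combination mice, 0.0493 for the negative clock limb in colitis, 0.0616 for each clock limb under the combination, 0.0689 for glucocorticoid genes with TNFR-Ig, 0.0493 in the combination against TNFR-Ig and 0.0491 for their departure from additivity. It was 0.0696 for the endoplasmic reticulum chaperones, 0.241 for accessory gland genes and 0.0616 for hair keratins.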
